A study of Homo sapiens with 3 samples.

How the data were processed

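Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in SC1, a human lymphoma cell line that the labels give as diffuse large B-cell lymphoma (DLBCL). The 3 samples were a ChIP with an antibody to CREBBP, a lysine acetyltransferase that acetylates histones, a ChIP with an antibody to histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and an input without antibody. Per the labels' protocols, sonicated nuclei were used and libraries were made with a commercial ChIP-seq kit. Each group held 1 sample, so no value has a replicate error. Peak names in both lists carry the words DMSO and rep2, which the labels do not explain. A peak list was used for 2 of the samples, and the input was not analysed here.

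Per the submitters' processing notes, fastp, Bowtie2, STAR and MACS2 were used and the genome build was hg19. Their roles, versions and settings are not given in the sources used here, nor is the library that served as control or whether samples were pooled. The authors deposited a list of narrow CREBBP peaks and a list of broad H3K27ac regions. Each list gives the authors' fold enrichment, a ratio of ChIP signal to expected background. Each also gives the authors' −log10 p and −log10 q and a score. The deposited CREBBP list gives a summit position for each peak, and the deposited H3K27ac values are taken to be means over each region, as the format defines them. In the CREBBP list the deposited score was 10 times −log10 p, cut to a whole number, in every peak, and the smallest −log10 p was 1.30. In the H3K27ac list the deposited score was 10 times −log10 q in all but 1 region. The CREBBP list therefore holds peaks down to a p-value of 0.05 with no limit on q. All these values are the authors' own and were used only to describe, rank and filter peaks within a list.

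Chromosomes 1 to 22 and X were used, which left out 128 CREBBP peaks and 17 H3K27ac regions. No intervals within a list overlapped. Positions are given on hg19, counted from 1. The reference at hand was a gene table of another assembly, GRCh38.p14, so no peak was assigned to a gene. The planned comparisons at promoters, in gene lists and at the MYC locus were not analysed here.

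A CREBBP peak counted as inside an H3K27ac region when they shared at least 1 bp. Chance overlap was taken from 1000 circular shifts, in which all CREBBP peaks of a chromosome were moved by one random distance and wrapped at the last position that either list covers. Two-sided circular permutation p-values come from these shifts, and 0.002 is the smallest that they can give. They describe where peaks lie in these libraries and not differences between cultures. Wide H3K27ac domains were the top 5% by covered length after joining regions within 12.5 kb. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. The text names, by a rule fixed before the data were examined, the 5 CREBBP peaks with the largest fold and the 5 widest H3K27ac regions. Any other position was chosen after its values were seen. Alternatives were a subset of stronger peaks or regions, a 50% overlap, the summit alone, local shifts of 10 to 50 kb, another domain definition and, added after seeing the data, CREBBP peaks of q at most 0.05.

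The depth of the libraries is not stated in the lists. In the CREBBP list it could be approached from the values. If fold is the number of fragments plus 1 over the background plus 1, and p is the upper Poisson tail, then fold and p together give both numbers. A whole number of fragments matched −log10 p within 0.001 for 215581 peaks, 99.99% of the list. The background was 1.30 fragments at 54.5% of peaks, and the median peak had 5 fragments at its summit (interquartile range 4 to 6). All fragment numbers and backgrounds given here are taken to be values at the summit of a peak, not totals over its width. Of 91001 higher backgrounds under 6 fragments, 44.6% were whole multiples of 0.924 fragments, 23.5% of the step that a 1 kb window would give and 32.0% of the step of a 10 kb window, within 0.0002. These steps used a fragment length equal to the shortest CREBBP peak, 248 bp. The same step was not sought in the H3K27ac list. The solved fragment numbers and backgrounds are inferences from the deposited values.

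Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap code was tested on simulated data made for the CREBBP and H3K27ac overlap. With planted shares of 10% and 50% inside regions it returned 9.65% and 50.3%, from 14964 and 14980 intervals. The solution for fragments returned the right number in 1000 of 1000 simulated peaks. These peaks followed the formula that the solution assumes, so they do not test the formula. The commonest background, 1.30 fragments, was not simulated, nor were many of the low folds seen at high backgrounds. Ratios of fold medians carry 95% intervals from 1000 bootstrap draws of 10 Mb blocks.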

Results

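The chromatin of SC1 lymphoma cells was mapped for the positions of CREBBP and for the regions marked by H3K27ac. The series title concerns CREBBP-deficient DLBCL and MYC expression, and the labels describe no CREBBP-deficient sample. The comparison open to these lists is where the acetyltransferase lay relative to the mark. The CREBBP list held 215598 peaks with a median width of 362 bp (interquartile range 293 to 481 bp), which covered 90.6 Mb. The H3K27ac list held 18263 regions with a median width of 1423 bp (919 to 2153 bp), which covered 34.1 Mb, or 1.12% of the extent of the chromosomes. Median fold enrichment, as the authors' peak caller gave it, was 2.17 in the CREBBP list and 4.92 in the H3K27ac list. A q of at most 0.05 was reached by 3901 CREBBP peaks, 1.81% of the list (95% interval 1.75 to 1.87%), and by 18144 H3K27ac regions, 99.3% of the list (99.2 to 99.5%). Of the CREBBP peaks, 80.7% had a −log10 q of 0. The CREBBP list had no limit on q, and its values belong to narrow peaks, while the H3K27ac values are means over broad regions. The medians and shares of the lists therefore do not compare their enrichment. There were no replicates, so differences between cultures could not be measured.

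CREBBP peaks lay inside H3K27ac regions more often than shifted peaks did. Of all CREBBP peaks, 10903 overlapped an H3K27ac region, 5.06% (95% interval 4.96 to 5.15%), against a mean of 1.38% in 1000 circular shifts (range 1.28 to 1.49%). This was a 3.67-fold excess (circular permutation p = 0.002 from the shifts, the smallest they can give). The excess was not shared by peaks of few fragments. The share inside was 0.030% at 3 fragments, 0.158% at 4, 0.360% at 5 and 0.991% at 6, below the shift mean of all peaks. It was 2.82% at 7 fragments, 93.2% at 20 to 29 and 16.0% at 100 or more. Shifts do not keep the background of a peak, and no shifts were run at matched background. Of the CREBBP peaks with q of at most 0.05, 2204 of 3901 lay in an H3K27ac region, 56.5% (54.9 to 58.1%), against 1.66% after shifts, a 34.1-fold excess (circular permutation p = 0.002). The remaining 1697 lay outside. Within this set, 878 peaks (22.5%) were more than 50 kb from any H3K27ac region. Just outside the regions, CREBBP peaks were fewer than after shifts. The first 1 kb beyond a region's edge held 1449 peaks, 0.571 times the mean of 100 shifts, and the stretch from 1 to 5 kb held 4926, 0.567 times that mean. At the peaks called, the median solved background was 2.77 fragments within 1 kb and 1.85 at 1 to 10 kb. More than 50 kb away it was 1.30. A higher background makes a peak harder to call, so the deficit need not reflect less CREBBP. That was not tested. From 5 to 50 kb the full list held 62522 peaks, 1.23 times the mean of the shifts. The peaks with q of at most 0.05 numbered 690 there, 0.725 times their mean. So many of these stronger peaks lay inside that the stretches outside must together fall below their shift means. Their ratios were 0.574 within 1 kb, 0.583 from 1 to 5 kb and 0.330 over 50 kb away. The value of 0.725 therefore does not show that stronger peaks avoid the stretch from 5 to 50 kb. Shifted peaks can fall in stretches that hold no CREBBP peak, such as chromosome 1 from 130 to 140 Mb. This can lower the number expected near H3K27ac regions. Over 50 kb away lay 63.0% of the full list, against 69.9% after shifts. No local shifts were run for these distances.

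The share inside H3K27ac regions rose with peak strength up to a point and then fell. It was 2.71% among the 173910 peaks with a −log10 q of 0 and 43.8% between 1.30 and 2. It reached 79.3% (75.1 to 83.1%) among the 411 peaks between 5 and 10. Above that it was 64.7% (56.5 to 72.3%) between 10 and 20, 40.3% (28.5 to 53.0%) between 20 and 50, and 11.8% (5.22 to 21.9%) among the 68 peaks of 50 or more. The background solved for those 68 peaks had a median of 205 fragments, against 1.30 at the peaks with a −log10 q of 0.

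**Figure D1:**
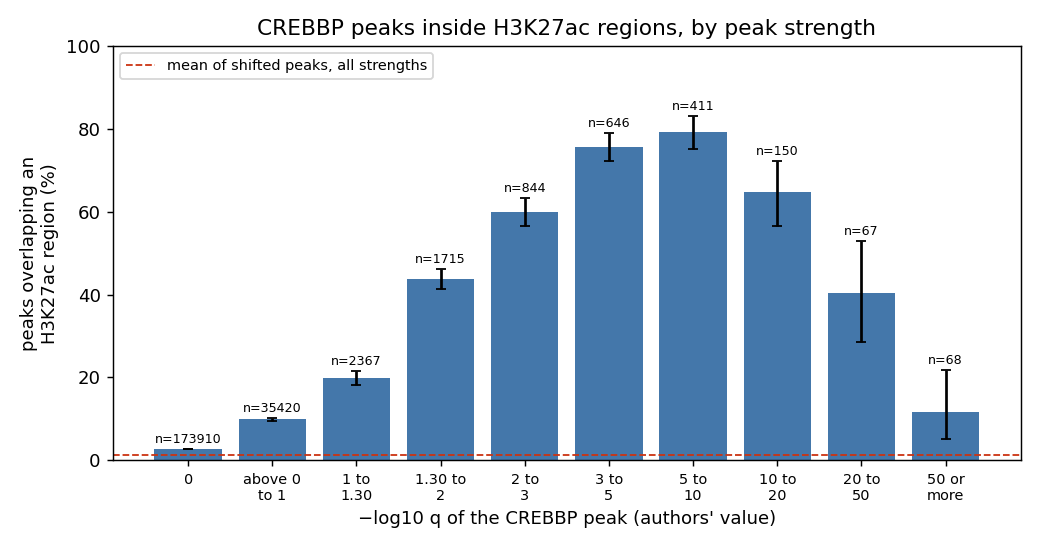
Share of CREBBP peaks that overlap an H3K27ac region (y axis, percent) by the authors' −log10 q of the peak (x axis); bars are shares, whiskers exact 95% binomial intervals, n the number of peaks, and the dashed line the mean of 1000 shifts over all strengths, 1.38%. The share climbs to 79.3% between 5 and 10 and falls to 11.8% at 50 or more.

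The 5 CREBBP peaks with the largest fold were 2 outside and 3 inside H3K27ac regions. The largest fold, 15.5, was at chromosome 19 from 36066493 to 36066901, where 43 fragments stood over a background of 1.85. This peak lay 29.2 kb from the nearest H3K27ac region. The second, with a fold of 11.4 and 126 fragments at its summit, was at chromosome 14 from 106327709 to 106329414. It lay inside an H3K27ac region of 3603 bp with a fold of 10.5. A peak at chromosome 6 from 133593863 to 133594153 had a fold of 11.3 and 25 fragments, and the nearest H3K27ac region was 457 kb away. The peak at chromosome 4 from 43912271 to 43913294 had a fold of 10.9 within an H3K27ac region of 2556 bp and fold 3.45. The peak at chromosome 11 from 62608390 to 62609467 had a fold of 10.4 and 144 fragments, within an H3K27ac region of 4175 bp and fold 5.05.

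Seen from the mark, 8940 of 18263 H3K27ac regions held a CREBBP peak, 48.95% (48.2 to 49.7%), against 14.4% after shifts, a 3.39-fold excess (circular permutation p = 0.002). A CREBBP peak with q of at most 0.05 was present in 2090 regions, 11.4% (10.99 to 11.9%), against 0.343% after shifts. Regions with a CREBBP peak of that strength were wider, with a median of 2173 bp (interquartile range 1434 to 3898 bp) against 1359 bp (878 to 2011 bp) for the other 16173 regions. Their median H3K27ac fold was 5.26 (3.56 to 7.88), against 4.85 (3.07 to 7.94). Across the 8940 shared regions the H3K27ac fold and the highest CREBBP fold had a Spearman rho of 0.0031 (bootstrap interval -0.015 to 0.022) and a Pearson r of 0.0093. This relation covers only regions that held a CREBBP peak, and fold divides by the background. It therefore need not follow the amount of CREBBP. The relation is across regions, which are not independent replicates. It was 1 of 4 relations computed across regions. The H3K27ac fold had a rho of 0.065 (0.039 to 0.087) with the highest number of CREBBP fragments. Region width had a rho of 0.44 (0.42 to 0.45) with the number of CREBBP peaks and of 0.14 (0.12 to 0.16) with the highest CREBBP fold. A wider region meets more peaks by its length alone, and more peaks can raise the highest fold. Neither rho was set against shifts. Over all regions, a CREBBP peak with q of at most 0.05 lay in 6.13% of the lowest decile by H3K27ac fold. That share was 14.2% in the sixth decile and 9.36% in the highest. Median widths of these deciles were 980, 1598.5 and 1267 bp, and the shares were not set against shifts.

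Wider H3K27ac regions held a CREBBP peak more often. In the narrowest decile, with a median width of 377 bp, 24.6% of regions held one (22.6 to 26.6%), and in the widest decile, with a median of 4938 bp, 84.6% did (82.9 to 86.2%). Shifted peaks fell in 5.76% and 33.9% of these regions, so the excess over shifts was 4.27-fold in the narrowest decile and 2.496-fold in the widest. With CREBBP peaks of q at most 0.05 the shares were 3.28% (2.52 to 4.21%) and 33.0% (30.8 to 35.2%). The excess over shifts was then 22.6-fold and 39.4-fold. In the widest decile the full list could not exceed a 2.95-fold excess, since shifted peaks already filled 33.9% of its regions, so its excess cannot be ranked against that of the narrowest. The difference between the deciles was not tested.

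**Figure D2:**
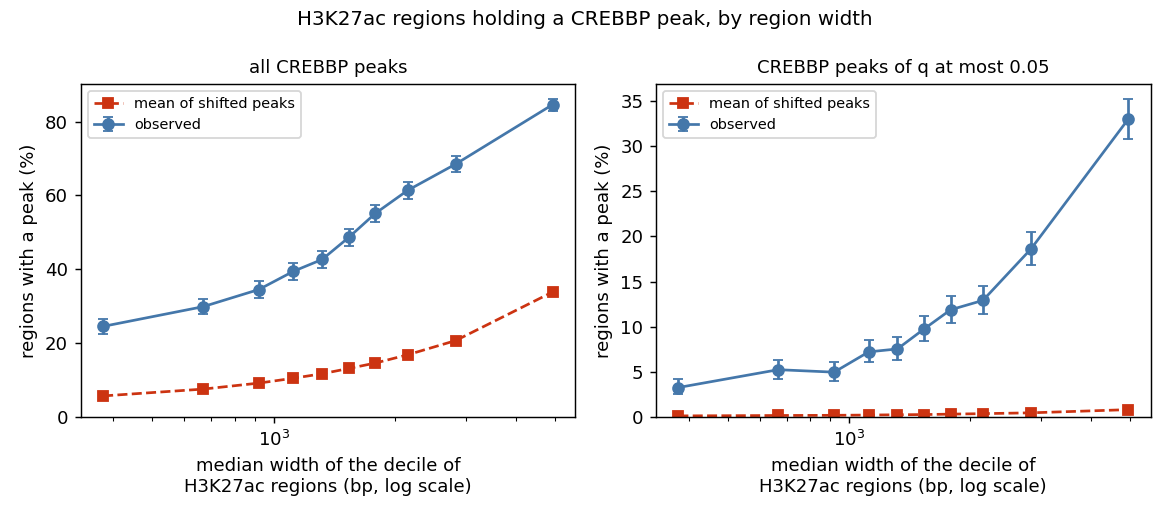
Share of H3K27ac regions that hold a CREBBP peak (y axis, percent) against the median width of each decile of regions (x axis, bp, log scale), for all CREBBP peaks and for those of q at most 0.05; circles are observed shares with exact 95% intervals and squares the mean of 200 shifts. The observed share runs from 24.6% to 84.6% with all peaks and from 3.28% to 33.0% with the stronger ones.

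The widest H3K27ac regions each held several CREBBP peaks. The widest spanned 38.8 kb on chromosome 22 from 23259369 to 23298200, with an H3K27ac fold of 7.31 and 7 CREBBP peaks, 3 of them with q of at most 0.05. The second spanned 35.1 kb on chromosome 14 from 106144228 to 106179286 and held 7 CREBBP peaks, 3 of that strength. The third spanned 33.5 kb on chromosome 6 from 27774440 to 27807930 and held 7, of which 5 passed. The fourth, 31.2 kb on chromosome 12 from 113486689 to 113517908, held 5, of which 3 passed. The fifth, 30.2 kb on chromosome 14 from 106024864 to 106055068, held 7, of which 4 passed. Of these 5 regions, 2 lay on chromosome 14.

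Joining neighbouring regions gave 13232 H3K27ac domains, of which the top 5% were 662 wide domains with at least 8.03 kb covered. They held 26.8% of the H3K27ac-covered length. At least 1 CREBBP peak lay in 648 of the 662 wide domains (97.9%) and in 6694 of the 12570 others (53.3%). A CREBBP peak with q of at most 0.05 lay in 370 wide domains (55.9%) and in 1571 of the others. Per kb of covered length the wide domains held fewer CREBBP peaks, 0.252 against 0.344, a ratio of 0.734 where shifts gave 0.864 (range 0.715 to 1.04, circular permutation p = 0.004). The call was lost with the stronger peaks. With q of at most 0.05 the densities were 0.0606 and 0.0660 per kb, a ratio of 0.918, where shifts had a mean of 0.828 and a range of 0.198 to 2.23 (circular permutation p = 0.659).

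The fold enrichment of CREBBP peaks was not higher inside H3K27ac regions over the whole list. Its median was 2.154 inside and 2.170 outside, a ratio of 0.993. Shifts gave a ratio of 1 in every draw, since most peaks share a few fold values, so they give no test of this difference. The number of fragments and the background were both higher inside. The median peak inside had 16 fragments at its summit (interquartile range 11 to 23) over a background of 6.87 (3.70 to 10.2). The median peak more than 50 kb away had 4 fragments at its summit (4 to 5) over a background of 1.30 (1.30 to 1.58). Between 10 and 50 kb from a region the median background was 1.42 (1.30 to 1.85).

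Peaks of like background were then compared, a step added after seeing the data. At a background of 1.30 the median fold was 3.04 inside and 2.17 outside, a ratio of 1.40 (1.20 to 1.40). The ratio was 1.25 (1.24 to 1.25) at backgrounds of 2 to 3 and 1.13 (1.098 to 1.16) at 5 to 10. It was 0.989 (0.934 to 1.04) at 10 to 20 and 0.770 (0.703 to 0.905) at 20 to 50. Of the 3204 peaks with a background of 10 to 20 fragments, 3007 lay inside H3K27ac regions (93.9%), against 0.226% of the 117394 peaks at the commonest background. The share of the stronger peaks inside also differed by background. Of the peaks with q of at most 0.05, 31 of 358 lay inside at the commonest background, 8.66% (5.96 to 12.1%), and 97 of 692 from there to 2 fragments, 14.02% (11.5 to 16.8%). The share was 39.0% from 2 to 3, 70.0% from 3 to 5, 89.0% (820 of 921) from 5 to 10 and 91.7% from 10 to 20, and 59 of 118 from 20 to 50. The background at a peak is itself an estimate from few fragments, so peaks of like estimated background need not have like true background.

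**Figure D3:**
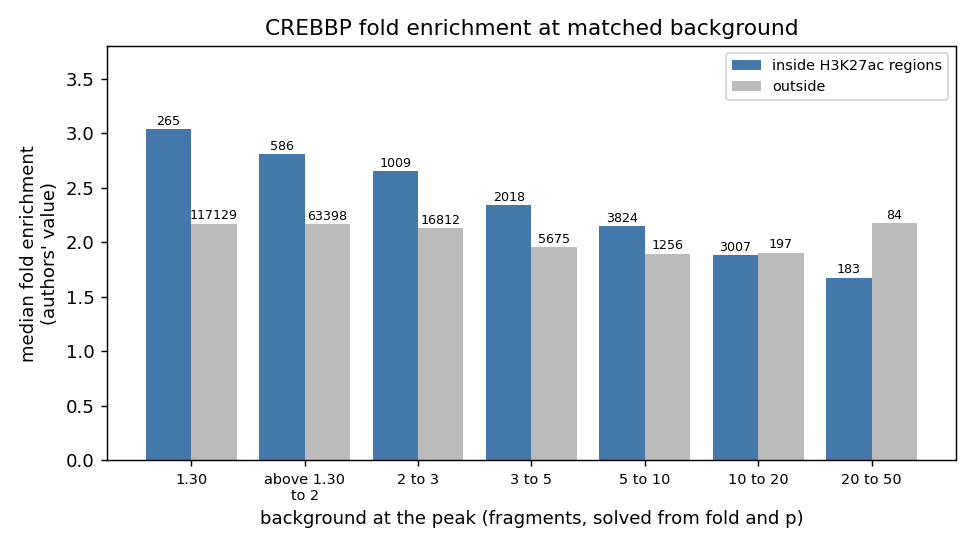
Median authors' fold enrichment of CREBBP peaks (y axis) inside (blue) and outside (grey) H3K27ac regions, by the background solved for the peak in fragments (x axis); numbers above the bars are peaks. The median is higher inside up to a background of 10 and lower inside at 20 to 50.

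The lists also differed in how they were spread over chromosomes. H3K27ac regions were densest on chromosome 19, at 18.9 per Mb, followed by chromosome 17 at 12.7 and chromosome 22 at 10.1. CREBBP peaks with q of at most 0.05 were also densest on chromosomes 19 and 17, at 2.55 and 2.13 per Mb. Over 23 chromosomes these densities had a Pearson r of 0.824 (permutation p = 1e-05, the smallest 100000 permutations can give) and a Spearman rho of 0.725 (permutation p = 0.00017, adjusted p = 0.00051 over 3 relations). Without chromosomes 19 and X, the farthest from the median CREBBP density, r was 0.729. The full CREBBP list showed no such relation, with an r of -0.039 (permutation p = 0.85) and a rho of -0.029 (permutation p = 0.90, adjusted p = 0.90). Without chromosomes 7 and X its r was -0.21. Its peaks were densest on chromosomes 7 and 8, at 108 and 94.3 per Mb, and sparsest on X at 19.4. The third relation, between the full list and its stronger peaks, had an r of 0.336 (permutation p = 0.12) and a rho of 0.208 (permutation p = 0.34, adjusted p = 0.51), and its r was -0.10 without chromosomes 7 and X.

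**Figure D4:**
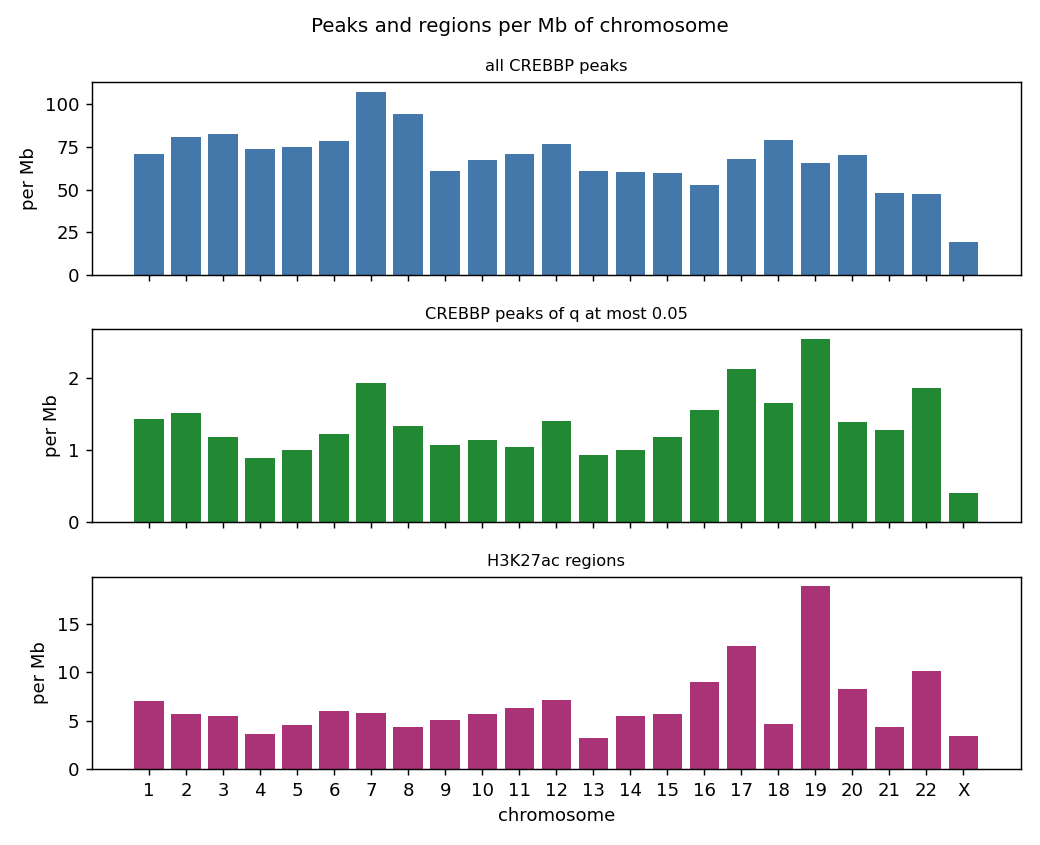
Number per Mb of chromosome (y axes) of all CREBBP peaks, of CREBBP peaks with q of at most 0.05 and of H3K27ac regions, for chromosomes 1 to 22 and X (x axis); each bar is 1 chromosome of 1 library. The full CREBBP list is highest on chromosome 7 at 108 per Mb, and both other sets are highest on chromosome 19.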

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

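The overlap of CREBBP peaks with H3K27ac regions, from either side, kept its direction and its circular permutation p of 0.002 under every alternative run. None of these overlap alternatives matched peaks on background. The share of CREBBP peaks inside ranged from 2.72% (only the upper 50% of H3K27ac regions by q) to 56.5% (CREBBP peaks of q at most 0.05). Its excess over shifts ranged from 3.04-fold (local shifts) to 34.1-fold. The share of H3K27ac regions holding a CREBBP peak ranged from 9.01% (50% overlap) to 51.0%. The excess of that share ranged from 2.87-fold (local shifts) to 33.3-fold (CREBBP peaks of q at most 0.05). The lower CREBBP density in wide domains, a ratio of 0.734, kept its call when the H3K27ac side was changed. The ratio was 0.718 (circular permutation p = 0.03) with the upper 50% of H3K27ac regions by q. It was 0.703 (circular permutation p = 0.002) without joining regions and 0.752 (circular permutation p = 0.002) with the top 10% of domains. The call was lost with fewer CREBBP peaks. The ratio was 0.761 (circular permutation p = 0.12) with the upper 50% of CREBBP peaks. With as many top peaks as there are H3K27ac regions it was 0.810 (circular permutation p = 0.855). With peaks of q at most 0.05 it was 0.918 (circular permutation p = 0.659), above the mean of the shifts but within their range of 0.198 to 2.23. The cause was not tested. The ratio of fold inside to outside stayed under 1 with the settings chosen before the data were examined, between 0.801 and 0.993. Most of these ratios have no usable test, since the shifts gave 1 in every draw. The shifts varied with as many top peaks as there are H3K27ac regions, where the ratio was 0.801 against 0.954 to 1.05. They also varied with peaks of q at most 0.05, where it was 0.815 against 0.848 to 1.15. Both sets were chosen by q, and at a given q a peak on a higher background needs a lower fold. Peaks inside stood on a higher background, so a lower fold inside follows in part from the choice. These shifts therefore give no usable test of the ratio either. At matched background, the ratio of fold turned to 1.40 at the commonest background. This alternative was chosen after seeing the data, as were the peaks of q at most 0.05. The ratio was 1.296 up to 2 fragments, 1.25 from 2 to 3, 1.197 from 3 to 5 and 1.13 from 5 to 10. From 10 to 20 it was 0.989, with an interval that includes 1. It kept the pooled direction, at 0.770 (0.703 to 0.905), from 20 to 50. The pooled value mixes these backgrounds, since 5.66% of peaks at 2 to 3 fragments but 93.9% at 10 to 20 lay inside. The settings foreseen for promoters, gene lists and the MYC locus were not run. No paired analysis was possible because each group held 1 sample. Depth limits what single CREBBP peaks can show, since the median peak had 5 fragments at its summit.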

Other observations

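The tests of mappable share and of acetylated chromatin per chromosome were chosen after the results were seen, as were the shares among peaks above the commonest background and the shares reaching q of at most 0.05 at matched background; the fold comparison at matched background was added after seeing the data, with its bound written before its own result, and the slope was recomputed per Mb lying over 50 kb from H3K27ac regions after a first result per Mb of whole chromosome had been seen. Among the wide H3K27ac domains, the one with the largest covered length lay on chromosome 18 from 53082808 to 53179199. Its 11 regions covered 55.9 kb and held 19 CREBBP peaks, none of which had a q of at most 0.05. The next, on chromosome 22 from 23242224 to 23298200, includes the widest single region. It covered 50.9 kb and held 9 CREBBP peaks, 5 of them with q of at most 0.05. The third, on chromosome 8 from 11269187 to 11357366, covered 48.0 kb with 9 CREBBP peaks, 2 of that strength. H3K27ac regions of the highest decile by fold, 12.0 or more, were narrow, with a median of 1267 bp. A CREBBP peak lay in 46.0% of them (43.7 to 48.3%), against 53.8% (51.5 to 56.1%) of the seventh decile, with folds of 5.87 to 7.13 and a median width of 1630 bp. Shifted peaks fell in 12.4% and 16.2% of them, so the excess over shifts was 3.70-fold in the highest decile and 3.33-fold in the seventh. The lowest decile, with folds of 1.00 to 2.23, was narrower still, with a median of 980 bp. A CREBBP peak lay in 38.7% of its regions (36.5 to 41.0%), a 3.58-fold excess over shifts.

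CREBBP peaks inside H3K27ac regions stood on a high background, 5.27 times the commonest one, and their fold was not higher over the whole list. DNA copy number shared with the flanks is argued against as the source of a background that high. Peaks 10 to 50 kb away had a median background 1.09 times the commonest, just within the bound of 1.1. Only called peaks enter this median, and 41.4% of them stood at the commonest background. It cannot exclude smaller gains of copy number. Control reads concentrated over acetylated chromatin, from shearing of open chromatin or from ChIP DNA in the control, stay open: the background of 58.3% of peaks inside, against 23.7% at 10 to 50 kb, fell on the step of a window of 1 fragment length, but among peaks above the commonest background, a comparison added after this result, the shares were 59.8% and 40.4%, and 51.2% over 50 kb away. Whether the stronger peaks inside reflect only more statistical power stays open. At backgrounds of 5 to 10 the fold inside was 1.13 times that outside, with an interval of 1.098 to 1.16 that reaches the bound of 1.1, and 21.4% of peaks inside but 8.04% outside reached a q of at most 0.05. These shares were 17.3% and 1.63% at 2 to 3 and 17.7% and 2.70% at 3 to 5, and turned to 21.8% inside and 29.9% outside at 10 to 20. At 20 to 50 they were 32.2% of 183 peaks inside and 70.2% of 84 outside. Like estimates mean like power only if the true backgrounds are alike, and noise in the estimated background could raise the fold and the share inside at low estimates, where the true background of peaks inside could be higher than that of peaks outside. That noise was not measured.

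The CREBBP peaks with a −log10 q of 20 or more lay mostly outside H3K27ac regions, 100 of 135. Their background outside was 131.7 times the commonest one, at a median of 172 fragments and a fold of 2.42, against 13.9 fragments and a fold of 5.34 for the 35 inside. Collapsed repeats or other places of very high coverage are a candidate explanation, and no repeat annotation was used to test it further. Of the 100 peaks, 80 had another of them within 1 Mb, and chromosomes 16, 10 and 2 held 20, 17 and 16. Binding at sites without the mark cannot be told apart for these peaks, because just 1 of them, the peak with the largest fold on chromosome 19, stood at a background within 1.5 times the commonest.

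The density of the full CREBBP list differed between chromosomes, from 19.4 per Mb on X to 108 on chromosome 7. No rise with the amount of acetylated chromatin was seen, since CREBBP and H3K27ac densities had a rho of -0.029 over 23 chromosomes. This rho has no interval and its bound was chosen after the results were seen. It cannot exclude a moderate relation, so acetylated chromatin as a cause stays open. A different mappable share alone is argued against by the ratio of peaks of 7 or more fragments to peaks of 4. More than 50 kb from any H3K27ac region, this ratio was 0.698 (0.641 to 0.760) on chromosome 18, 0.549 on 7, 0.423 on 19 and 0.393 on 8. It was 0.095 (0.072 to 0.123) on X, a 7.36-fold range around a median of 0.235. This ratio did not always go with the density of the full list. It was 0.374, 0.371 and 0.350 on chromosomes 13, 21 and 22, which held 61.1, 47.9 and 47.4 CREBBP peaks per Mb. Those densities divide by the whole extent of a chromosome, which includes stretches with few or no peaks. The window from 0 to 10 Mb held 0 peaks on chromosomes 13 and 22 and 106 on 21. Part of the mismatch can therefore come from the mappable share, and it does not count against copy number. DNA copy number of the cell line may contribute and stays open. The log density of peaks of 7 or more fragments rose on that of peaks of 4 with a slope of 1.34. Its bootstrap interval of 0.187 to 1.68 includes 1. The slope was 0.747 without X and 0.195 without 7, 8 and X. The densities behind these slopes also divide by stretches with few or no peaks, such as the first 10 Mb of chromosome 13. How far this changed the slopes was not tested. On chromosome 8, windows of 10 Mb between 60 and 130 Mb held 1113 to 1242 CREBBP peaks, those below 60 Mb held 626 to 911, and the window from 130 to 140 Mb held 611.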
